A study of Sus scrofa with 8 samples.

How the data were processed

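Skin of Yorkshire swine was sampled from 2 pigs, called pig 13 and pig 14 in the labels. In each pig 2 sites received an intradermal injection of 200 ng of IL-15 in 100 µl of saline and were biopsied 3 h later, and 2 further sites were biopsied without injection. This gave 4 injected and 4 control biopsies. Biopsies of the same pig are not separate animals. The p-values of single genes below therefore measure the spread between sites within these 2 animals and not the spread between pigs. Per the labels' protocols, total RNA was extracted from the whole biopsy with a kit for lipid-rich tissue and depleted of ribosomal RNA with RiboZero Gold. Whether the counting used strand is not given in the sources used here, so reads of a gene and of an overlapping or antisense partner may not be told apart.

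The submitters' processing notes name bcl2fastq, STAR 2.5.1a, featureCounts 1.4.6-p5 from the Subread package and the pig genome build Sscrofa11.1. Per the file headers, the authors deposited whole-number read counts per Ensembl gene, as a table of all 8 biopsies and as a file for each biopsy. The file of each biopsy also holds CPM, which the authors computed from the counts assigned to genes in that biopsy, and RPKM, which the authors computed as CPM per kilobase of gene length. The deposited CPM and RPKM columns were only compared with the counts, and every test ran on counts. The counts of the single files equalled those of the series table for every gene present in both. The deposited file of the pig 13 control biopsy from site 7b ended after 607 complete genes, so that biopsy was read from the series table, whose total equalled the total implied by the CPM of those genes.

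The series table had 32388 rows for 31907 distinct Ensembl genes. The 425 genes on several rows had identical counts on each and were kept once. A symbol was found for 18265 genes, of which 16679 symbols came from the table itself, 822 from a table of gene names and 764 from a RefSeq gene table. Gene positions are those of Sscrofa11.1 as the deposited files give them. Total counts per biopsy ran from 28471089 to 36070107.

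Genes with enough counts for their group were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3 with its default minimum count of 10, which left 19862 genes. Libraries were scaled by TMM. The main test was edgeR's quasi-likelihood F test with robust estimation, with treatment and pig in the model, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. A model with an interaction of pig and treatment asked whether the response differed between the 2 animals. Fold changes are log2 values of injected over control biopsies with their standard error, and CPM values are after TMM scaling, with the SD over 4 biopsies. The biological coefficient of variation was 19.8%.

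The pig was kept as a block because the labels say which animal each biopsy came from. Checked on the data, the deviations of injected and control biopsies from their group means correlated between 0.25 and 0.54 within a pig and between -0.49 and -0.28 across pigs. No pair of biopsies agreed within sampling noise.

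Before the data were examined, 28 gene lists with 583 symbols were fixed, of pathways, cell type markers and treatment responses, and 515 of the symbols had a gene in the table. The 27 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. At this preset the members of a list count as nearly independent, so a small camera p can reflect many genes that vary together. Such a p does not by itself measure the spread between sites or between pigs. The estimated correlation ran from -0.042 for melanocyte to 0.80 for hair follicle markers, and was 0.45 for cytokine and NF-kB genes. Camera with an estimated correlation and fry were run beside the preset test. The list of keratinocyte stress genes had fewer than 5 tested members and was not tested. The genes named in the text were also set by a rule made before the data were examined. It took up to 10 called genes with the largest rise, a mean of at least 1 CPM and every injected biopsy above every control biopsy of its pig. It added the 5 rising genes with the smallest p, up to 5 called genes with the largest fall, the members of each list with the smallest p (3 in lists called by camera, otherwise 1) and a set of IL-15 receptor and signalling genes whatever their values, and for the interaction the 5 genes with the smallest p. Not every gene that the rule takes is named in the text. Genes named outside this rule are marked as chosen after their values were seen.

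The procedure was tested on simulated data. Counts of 19862 genes were drawn from the means and spread of the real biopsies for the comparison of injected with control sites, with 200 genes changed. The changed genes were taken only from genes above 1 CPM on average, so the shares below do not cover genes with fewer counts. Each count was drawn separately, so joint shifts of many genes in a biopsy were not simulated. With a change of 1.5-fold, 13% of the changed genes were called. With a change of 2-fold this share was 71.5%, and with 4-fold it was 98%. Between 1 and 15 unchanged genes were called in these runs.

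Alternatives fixed beforehand were the size factors of DESeq2, library size without TMM, no filter beyond a total count above 0, a filter of at least 1 CPM in at least 4 biopsies, the Wald test of DESeq2 1.42.0 and limma-voom with sample quality weights. Others were no pig term, the pig as a random effect, counts summed per pig and treatment, removal of mitochondrial and rRNA genes, each pig alone, a test against a 1.5-fold change, and leaving out each biopsy in turn. Scores of keratinocyte and adipocyte markers as covariates were added after seeing the data. A score is the mean over list members of the log2 CPM minus the mean of that gene over the 8 biopsies.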

Results

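RNA from 8 skin biopsies of 2 pigs was sequenced to ask which genes respond within hours to IL-15 placed in the dermis. IL-15 is a cytokine that signals through the shared gamma chain receptor and the kinases JAK1 and JAK3, and the design text states that strongly induced genes were sought as readouts for a topical inhibitor of these kinases. The injected group held 4 biopsies, from sites 12c and 12d of pig 14 and sites 12c and 12e of pig 13, each taken 3 h after 200 ng of IL-15. The control group held 4 biopsies without injection, from sites 6b and 7e of pig 14 and sites 6b and 7b of pig 13. Total counts were between 28471089 and 36070107 per injected biopsy and between 28730579 and 33567610 per control biopsy. Annotated rRNA genes held 1.24% to 1.86% of the counts in injected biopsies and 1.78% to 3.27% in controls. Genes of the mitochondrial genome held 3.10% to 3.90% and 3.09% to 4.69%, respectively. The first principal component held 63.1% of the variance of the 1000 most variable genes and separated the 2 pigs.

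Injected sites had higher levels of 7 genes than control sites of the same animals. Of these, 3 were HOX genes, transcription factors that mark position along the body axis, and HOXA10 and HOXC10 had the largest differences. HOXA10 was 77.7-fold higher, at 5.49 ± 2.01 CPM in injected and 0.069 ± 0.058 CPM in control biopsies (SD, n = 4), from 86 to 215 counts per injected biopsy and 1 to 4 per control. HOXC10 was 12.2-fold higher and HOXA9 7.23-fold higher. PTX3, a secreted pentraxin of innate immunity, rose 7.45-fold, from 5.72 ± 2.59 to 40.6 ± 7.79 CPM (SD, n = 4). RGS16, a regulator of G protein signalling, rose 3.71-fold, SPSB1, a SOCS box adaptor of ubiquitin ligases, 2.45-fold, and CHAC1, an enzyme that degrades glutathione, 2.02-fold.

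All 7 genes were higher in every injected biopsy than in every control biopsy of the same pig. In edgeR's quasi-likelihood test the log2 fold change of HOXA10 (ENSSSCG00000021204, chromosome 18, 45393712 to 45403257) was 6.28 ± 0.39 (SE, adjusted p = 0.00021). HOXA9 (ENSSSCG00000028997, chromosome 18, 45408377 to 45411510) had 2.85 ± 0.22 (adjusted p = 0.0009). HOXC10 (ENSSSCG00000022728, chromosome 5, 19197807 to 19202970) had 3.61 ± 0.30 (adjusted p = 0.0014). SPSB1 (ENSSSCG00000035940, chromosome 6, 69720806 to 69791127) had 1.29 ± 0.14 (adjusted p = 0.0105). CHAC1 (ENSSSCG00000038521, chromosome 1, 130360513 to 130363308) had 1.02 ± 0.12 (adjusted p = 0.0182). PTX3 (ENSSSCG00000011727, chromosome 13, 97273594 to 97279569) had 2.90 ± 0.30 and RGS16 (ENSSSCG00000015550, chromosome 9, 123913172 to 123956800) 1.89 ± 0.22, both with an adjusted p of 0.0296. These spans are the annotated protein-coding genes in Sscrofa11.1, and reads were counted per gene. No gene was called lower among the 19862 tested, with 428 lower and 474 higher at an unadjusted p under 0.05, where 993 in both directions are expected by chance. DESeq2 called 48 genes higher and 10 lower. Among the lower ones was the 18S rRNA gene RN18S, chosen after its values were seen (log2 fold change -1.52, adjusted p = 1.1e-05 by DESeq2). It was at 1487 to 3559 CPM in injected and 3658 to 13619 CPM in control biopsies, and edgeR did not call it (adjusted p = 0.37). Whether the depletion of ribosomal RNA differed between the groups was not tested. The calls of the 4 genes other than HOX genes depended on single biopsies. Only the 3 HOX genes stayed called without the pig 14 injected biopsy from site 12d or the pig 14 control biopsy from site 6b. Without the pig 13 injected biopsy from site 12c SPSB1 was called beside them, and without the pig 13 control biopsy from site 6b PTX3 was, with 4 genes called higher each time. All injected sites carried the number 12 and all control sites the numbers 6 or 7, so site and treatment could not be separated, and no site received saline alone.

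**Figure D1:**
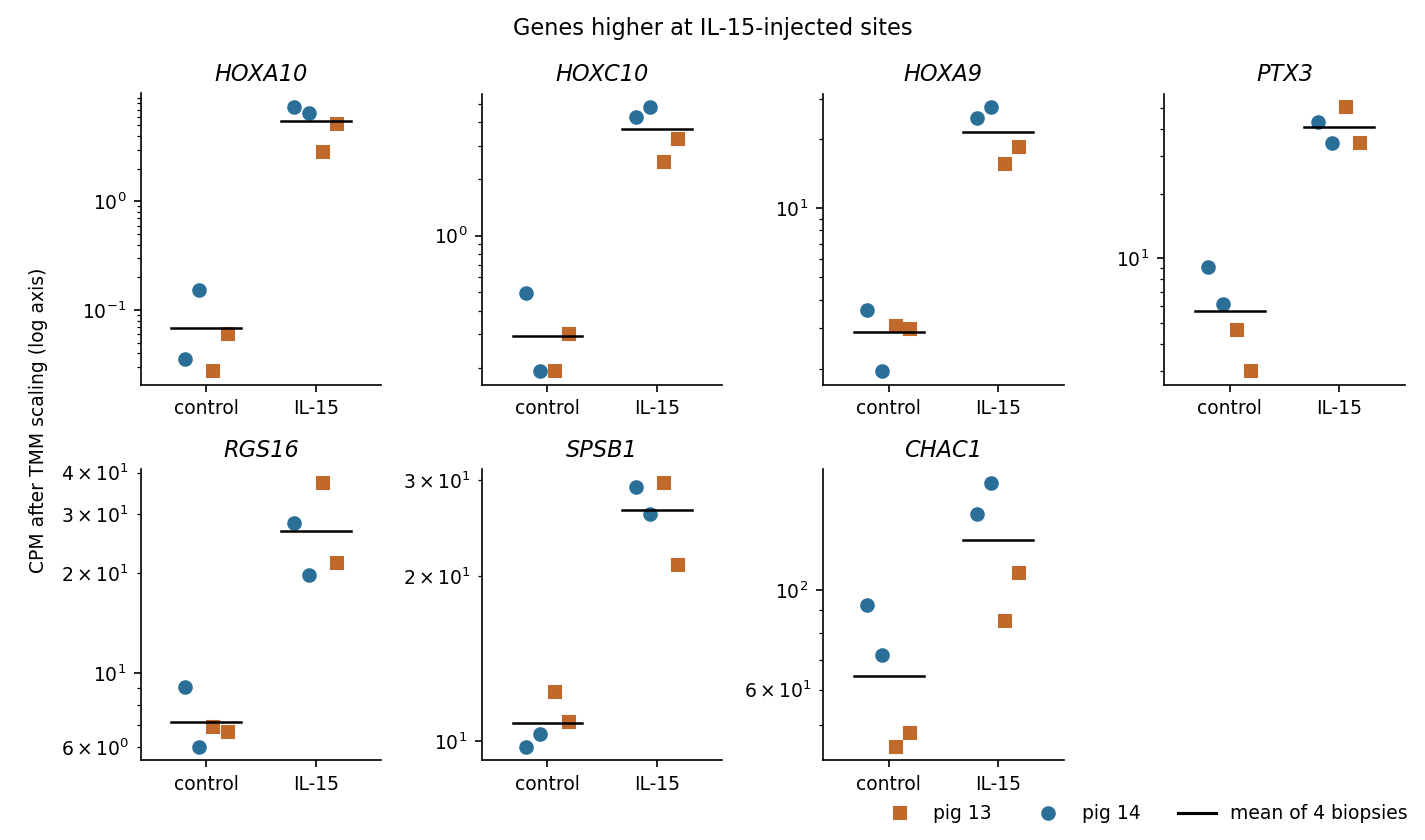
Level of each of the 7 called genes (CPM after TMM scaling, log axis) in the 4 control and 4 IL-15-injected biopsies, with squares for pig 13, circles for pig 14 and a line at the mean of 4 biopsies. HOXA10 has a mean of 0.069 CPM in controls and 5.49 CPM at injected sites, and CHAC1 shows the smallest change, at 2.02-fold.

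Within the HOX family the difference lay in particular members of the A and C clusters. This family was examined after its values were seen. Of 31 tested HOX genes, 6 passed when adjusted over the family alone, namely HOXA5, HOXA9, HOXA10, HOXA11, HOXA13 and HOXC10. HOXA11 had a log2 fold change of 2.55 ± 0.54 and HOXA13 of 1.78 ± 0.39, but neither passed over all genes in edgeR (adjusted p = 0.559 and 0.607). HOXA5 had 0.87 ± 0.20 (adjusted p = 0.689 over all genes in edgeR). DESeq2 called HOXA11 (adjusted p = 0.00024), HOXA5 (adjusted p = 0.0151) and HOXA13 (adjusted p = 0.0281) over all genes. The other members with paralog numbers 9 or 10 were not called, HOXC9 of the C cluster among them, with values of 0.05 ± 0.20 for HOXB9, 0.13 ± 0.16 for HOXC9, 0.17 ± 0.16 for HOXD9 and -0.05 ± 0.28 for HOXD10.

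**Figure D2:**
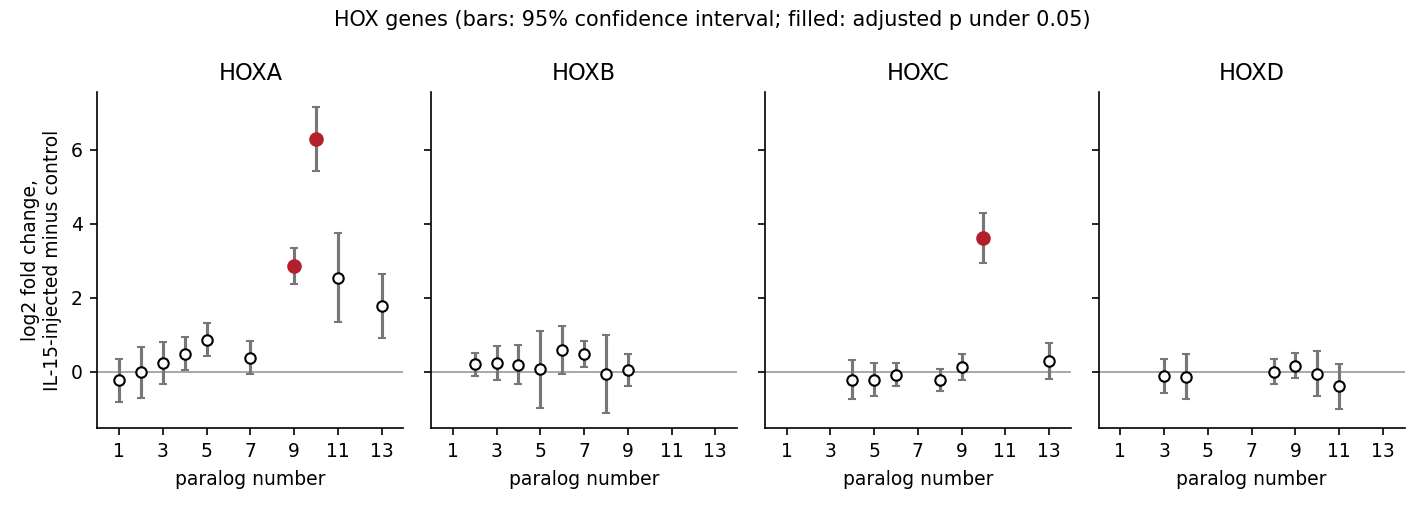
Log2 fold change between IL-15-injected and control sites of the 31 tested HOX genes against paralog number, in 1 panel per cluster, with 95% confidence intervals as bars and filled points for genes called over all genes. HOXA9, HOXA10 and HOXC10, the HOX genes that edgeR called, are filled, at 2.85, 6.28 and 3.61.

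Cytokine and NF-kB response genes were the list with the largest median shift toward injected sites and the smallest camera p. Of its 28 tested members edgeR called 1 higher over all genes tested (PTX3), and 15 rose when adjusted over the list alone, with none lower. Among these were TNF, an early cytokine (log2 fold change 1.41 ± 0.24), and TNFAIP6, a hyaluronan-binding protein made in inflammation (1.28 ± 0.29). Others, chosen after their values were seen, were IL6 (3.00 ± 0.61), the chemokine CCL2 (2.64 ± 0.54) and the adhesion molecule ICAM1 (1.21 ± 0.27). DESeq2 also called TNF, ICAM1, CCL2, TNFAIP6 and IL6 over all genes (adjusted p from 0.00015 to 0.0067). The list median was 0.69 and camera called it (adjusted p = 1.2e-32), but not with an estimated correlation (adjusted p = 0.324 with an estimated correlation). Its score was between 0.19 and 0.64 in injected and between -1.27 and 0.14 in control biopsies. The neutrophil chemokine CXCL8, also chosen after its values were seen, had -1.33 ± 1.32 and reached 19.97 CPM in the pig 13 control biopsy from site 7b, against 0.24 to 2.12 in the other controls.

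Immediate early and wounding genes formed the next list that camera called upward (adjusted p = 1.3e-08, and adjusted p = 0.357 with an estimated correlation). Of 30 tested members none was called over all genes, and 6 rose when adjusted over the list alone, with a median of 0.09. The AP-1 subunit FOSB had 1.54 ± 0.25 and the transcription factor EGR1 0.68 ± 0.14. Targets of the gamma chain and STAT5 were called upward (adjusted p = 9.6e-05, and adjusted p = 0.324 with an estimated correlation). Of 21 members none was called over all genes and 2 rose when adjusted over the list alone, the phosphatase DUSP5 (0.51 ± 0.11) and MYC (0.42 ± 0.11), and TNFRSF18 had 0.53 ± 0.17. The largest change of this list was that of SOCS3, chosen after its values were seen (1.86 ± 0.63). SOCS3 did not pass in edgeR's test when adjusted over the list alone (adjusted p = 0.127). Type I interferon response genes had a median of 0.23 and were called upward (adjusted p = 7.5e-08, and adjusted p = 0.644 with an estimated correlation). None of the 32 members passed over all genes or when adjusted over the list alone, and RSAD2 had 0.65 ± 0.22, ISG15 0.67 ± 0.26 and the RNA sensor DDX58 0.80 ± 0.28.

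Camera at its preset correlation also called 5 lists of cell type markers, none of which passed with an estimated correlation or with fry. Markers of differentiated keratinocytes, the cells of the outer epidermis, were called downward with a median of -0.42 (adjusted p = 1.3e-07, and adjusted p = 0.609 with an estimated correlation), where KLK5 had -0.42 ± 0.13, CDSN -0.53 ± 0.18 and DSC1 -0.48 ± 0.20. Neutrophil markers were called downward with a median of -0.30 (adjusted p = 0.0277, and adjusted p = 0.644 with an estimated correlation), where MMP25 had -0.66 ± 0.30, CXCR2 -0.50 ± 0.31 and S100A8 -1.12 ± 0.73. None of the 17 keratinocyte and 18 neutrophil members passed over all genes or when adjusted over the list alone. Endothelial markers were called upward (adjusted p = 0.0022, and adjusted p = 0.683 with an estimated correlation), and 2 of 17 rose when adjusted over the list alone, ACKR1 (0.56 ± 0.09) and CLDN5 (0.62 ± 0.15), beside 0.35 ± 0.12 for ESAM. Hair follicle markers were called upward (median 0.25, adjusted p = 0.00023, and adjusted p = 0.683 with an estimated correlation), with 0.54 ± 0.29 for KRT27, 0.56 ± 0.31 for KRT74 and 0.47 ± 0.32 for KRT71. Adipocyte markers were called upward (median 0.42, adjusted p = 0.0316, and adjusted p = 0.808 with an estimated correlation), with 0.90 ± 0.60 for PPARG, 1.05 ± 0.82 for CIDEC and 0.42 ± 0.37 for FASN. The adipocyte score was 0.32 and 0.52 at injected and -0.85 at both control sites of pig 13, but 0.66 and -0.78 at injected and 0.85 and 0.13 at control sites of pig 14. No member of the hair follicle and adipocyte lists passed over all genes or when adjusted over the list alone.

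Camera thus called 9 of 27 lists, 7 upward and 2 downward, and 0 with an estimated correlation or with fry's directional test. Fry's test for change in either direction passed 3 lists, those of STAT5 targets (adjusted p = 0.0012) and of NF-kB and immediate early genes (adjusted p = 0.0173 for both). When the 8 biopsies were split otherwise with 2 biopsies of each pig on both sides, 10 of the other 17 splits also gave at least 9 list calls. Without the pig 14 control biopsy from site 6b 15 lists were called, among them gland markers and monocyte markers with the direction turned (adjusted p = 0.015 and 0.0227 by camera). The calls of the hair follicle, endothelial, neutrophil and adipocyte lists each ended without at least 1 single biopsy, with the highest adjusted p at 0.526, 0.242, 0.759 and 0.719.

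**Figure D3:**
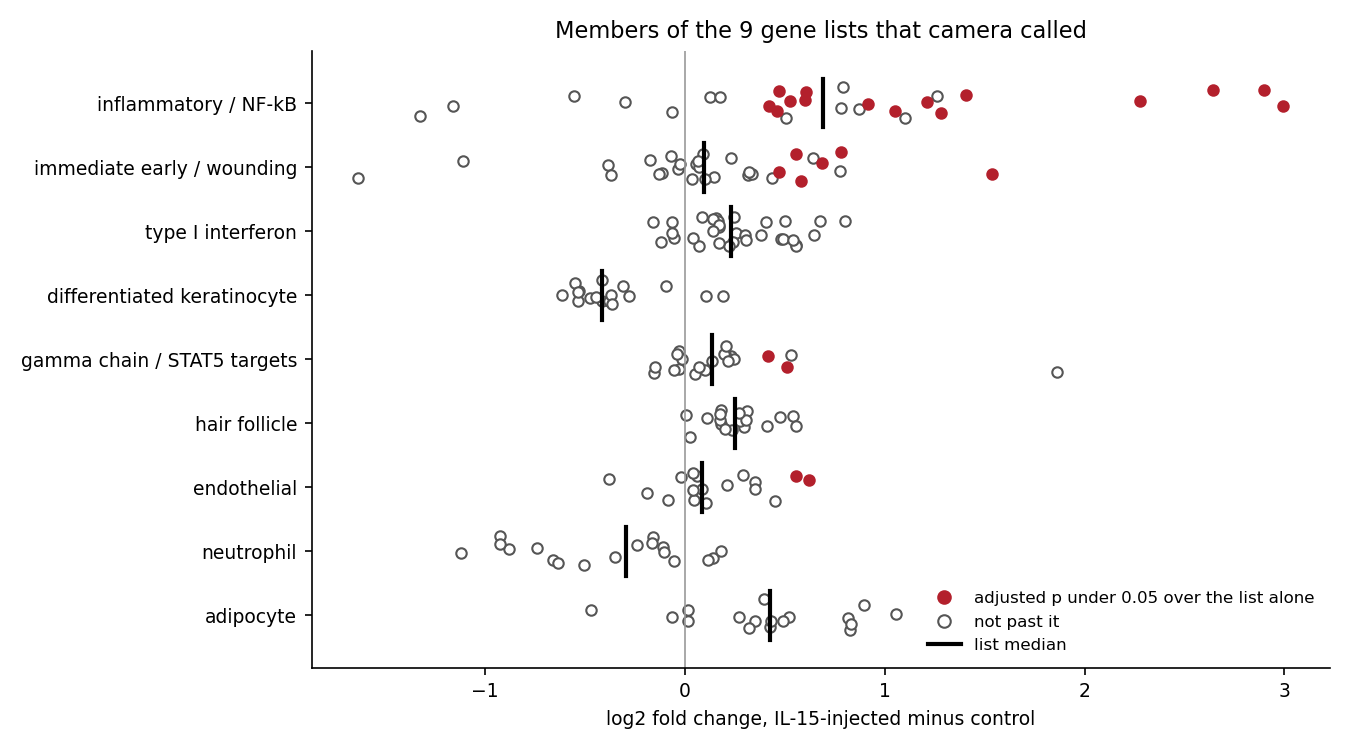
Log2 fold change between IL-15-injected and control sites of each tested member of the 9 lists called by camera, with a thick line at the list median and filled points for members that pass when adjusted over the list alone. In the list of cytokine and NF-kB response genes 15 of 28 members are filled and the median is 0.69.

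The other 18 tested lists were not called, with adjusted p between 0.116 and 0.874 and medians between -0.23 and 0.18. Among immune cells these were lists of T cells (ICOS -0.92 ± 0.37), cytotoxic effectors (CCL4 2.48 ± 0.51), B and plasma cells (BLK -0.62 ± 0.28), monocytes, macrophages and dendritic cells (CCR2 -0.31 ± 0.22), mast cells (KIT -0.20 ± 0.12) and MHC class II (SLA-DOA -0.33 ± 0.19). Among skin and other tissue components they were lists of basal keratinocytes (KRT5 0.38 ± 0.25), fibroblast matrix (THY1 0.39 ± 0.18), smooth muscle and pericytes (CSPG4 0.38 ± 0.11), skeletal muscle (TNNI2 0.53 ± 0.19), glands (MC5R -1.06 ± 0.57), melanocytes (EDNRB 0.44 ± 0.12) and red blood cells. The remaining ones were interferon gamma response (IRF1 1.07 ± 0.28), type 2 and atopic dermatitis genes (TSLP -0.87 ± 0.39), heat shock (BAG3 0.19 ± 0.11), cell cycle (TPX2 -0.46 ± 0.20) and the receptor and JAK-STAT components (STAT6 0.17 ± 0.08). None of these genes was called over all genes by edgeR, and CCL4 and EDNRB passed when adjusted over their lists alone. DESeq2 called CCL4 (adjusted p = 0.0027) and IRF1 (adjusted p = 0.0118) over all genes.

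The genes of the IL-15 pathway itself were not called. IL15 had a log2 fold change of 0.07 ± 0.30, its private receptor chain IL15RA 0.21 ± 0.24, the shared chains IL2RB -0.06 ± 0.15 and IL2RG -0.22 ± 0.23, and the kinases JAK1 0.05 ± 0.11 and JAK3 -0.05 ± 0.25. STAT5A had 0.12 ± 0.10 and STAT5B 0.05 ± 0.09. CISH, a feedback inhibitor induced by STAT5, had 0.23 ± 0.10 (95% confidence interval 0.01 to 0.45, adjusted p = 0.964 over all genes), and SOCS1 had -0.03 ± 0.12. The signs of IL15, IL2RB, IL2RG, JAK1, JAK3 and SOCS1 turned in at least 1 alternative setting or when a biopsy was left out. IFNG was too low to test, with 0 to 4 counts in injected and 0 to 6 in control biopsies, and a count of 0 allows up to 0.0832 to 0.0990 CPM in the biopsies where none was seen.

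The pig 13 control biopsy from site 7b differed from the other controls in both tissue and inflammatory genes. The collagen gene COL1A1 was at 8115 CPM there, against 38265 to 99273 in the other controls, and the basal keratin KRT5 at 10850 against 3171 to 6309. SOCS3, a feedback inhibitor of cytokine signalling, was at 29.0 CPM, against 3.60 to 8.44 in the other controls and 36.8 to 47.2 in injected biopsies. These genes were chosen after their values were seen. The fit without this biopsy is given because such genes were high in it. The calls of that fit are therefore conditional on the removal, which left pig 13 only the control from site 6b. That control had the lowest cytokine and NF-kB list score of all biopsies, -1.27, against -0.29 and -0.38 in the pig 14 controls. The pig 13 changes in that fit are thus measured against this low control. IL4R and FOS were at 57.938 and 34.009 CPM in the removed biopsy, above the lower injected value of pig 13 (33.992 and 33.355 CPM). The same held in the removed biopsy for ZC3H12A (49.989 against 22.157 CPM), SBNO2 (156.63 against 115.16) and BCL3 (40.401 against 28.526). These are also among the genes that the fit without it called higher. SOCS3, IL6, RND1, ADAMTS4, ICAM1 and FOSB were lower there than in both injected biopsies of pig 13. Without the biopsy from site 7b 19 genes were called higher and none lower. They included SOCS3 (log2 fold change 2.83 ± 0.20, adjusted p = 0.001), IL6 (4.09 ± 0.40, adjusted p = 0.0061), the GTPase RND1 (3.11 ± 0.27, adjusted p = 0.0014), the aggrecan-cleaving protease ADAMTS4 (2.90 ± 0.27, adjusted p = 0.0133), ICAM1 (1.54 ± 0.18, adjusted p = 0.0214), FOS (1.19 ± 0.16, adjusted p = 0.0263), FOSB (1.78 ± 0.23, adjusted p = 0.0308) and the receptor chain IL4R (0.71 ± 0.10, adjusted p = 0.0418). PTX3 and RGS16 kept log2 fold changes of 2.86 ± 0.38 and 1.85 ± 0.27 but were no longer called (adjusted p = 0.136 and 0.105). In that fit 20 of the 28 cytokine and NF-kB genes, 12 of the 30 immediate early genes and 4 of the 21 STAT5 targets rose when adjusted over the list alone. No list passed with an estimated correlation, where the smallest adjusted p was 0.0533, for the STAT5 targets, and was 0.0825 for both other lists. The calls of hair follicle and neutrophil markers ended without this biopsy, with medians of -0.02 in place of 0.25 and -0.086 in place of -0.30, and so did that of adipocyte markers, with 0.16 in place of 0.42. Differentiated keratinocyte markers stayed called with a median of -0.24 in place of -0.42, and immediate early genes with 0.39 in place of 0.09. Camera then called basal keratinocyte markers (adjusted p = 1.1e-05), type 2 and atopic dermatitis genes (adjusted p = 0.0064) and receptor and JAK-STAT components (adjusted p = 0.0319) upward, with adjusted p between 0.441 and 0.74 with an estimated correlation.

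**Figure D4:**
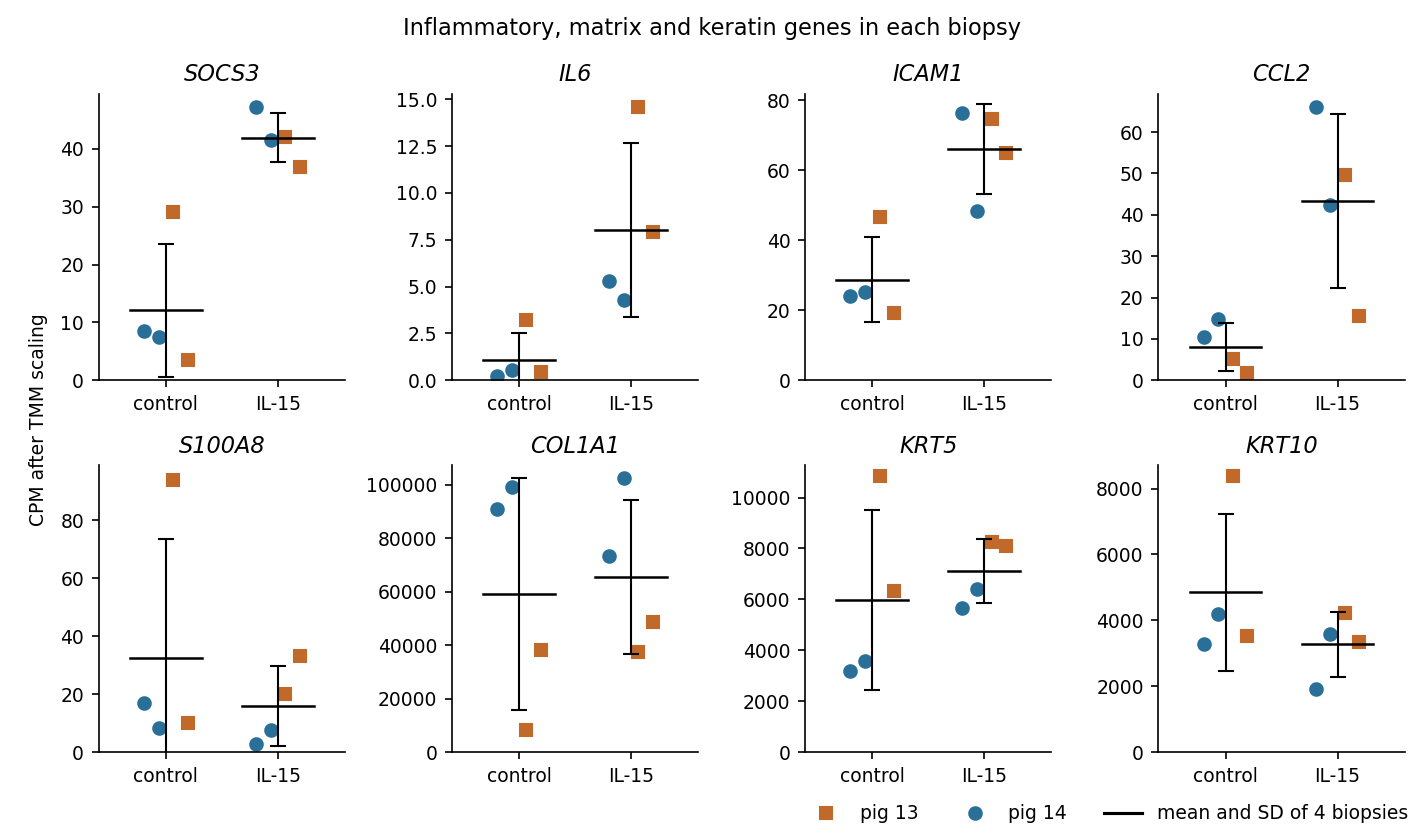
Level (CPM after TMM scaling, linear axis from 0) of inflammatory genes, the neutrophil gene S100A8, a collagen and keratins in each of the 4 control and 4 injected biopsies, with squares for pig 13, circles for pig 14 and the mean and SD of 4 biopsies in black. The highest control square of SOCS3, at 29.0 CPM, the highest of S100A8, at 93.9 CPM, and the lowest of COL1A1, at 8115 CPM, belong to the same biopsy, from site 7b of pig 13.

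Whether the response differed between the 2 pigs was asked with an interaction term, which compares these 2 animals only. No gene was called by edgeR (smallest adjusted p = 0.25), while DESeq2 called 86. At an unadjusted p under 0.05 edgeR had 1633 genes, more than the 993 expected by chance. The 5 named genes with the smallest p were TENM2, SLCO2A1, PAQR9, ME1 and RHOQ. The response of pig 14 minus that of pig 13 was 1.47 ± 0.22 on the log2 scale for TENM2, 1.61 ± 0.24 for the prostaglandin transporter SLCO2A1, -1.35 ± 0.20 for PAQR9, -2.26 ± 0.32 for malic enzyme ME1 and -1.21 ± 0.19 for RHOQ. The adipocyte markers PPARG (-2.04 ± 0.86), CIDEC (-2.81 ± 1.10) and FASN (-1.63 ± 0.44) had the same sign as ME1 and PAQR9 and were not called. With pig 13 alone ME1 and PAQR9 were called higher at injected sites together with the adipocyte genes PLIN1, ADIPOQ, LEP and FABP4, which were chosen after their values were seen. Without the pig 13 control biopsy from site 6b 318 genes were called, and without the pig 14 injected biopsy from site 12d 10 genes.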

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

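The tests that weigh explanations here were chosen only after the results were seen. Among 190 groups of 4 biopsies checked for a value far from the others, 6 were picked out, where about 9.5 would be expected if chance picked 1 in 20. Each was the highest or lowest of its group, and its gap to the nearest other value, as a share of the range of the group, exceeded the 95% critical value of Dixon's test. The rate of 1 in 20 holds for independent values of a single normal distribution. Each group here held 2 biopsies of each of 2 pigs that differed, so 6 cannot be read as fewer than chance gives. S100A8 was at 93.86 CPM in control replicate 3 (pig 13, site 7b), against 8.48 to 17.0 in the other controls. MYC was at 84.97 CPM and KLK5 at 28.05 CPM in control replicate 4 (pig 13, site 6b), against 69.7 to 71.6 and 39.1 to 41.0. TSLP was at 0.9162 CPM in control replicate 2 (pig 14, site 6b), against 0.39 to 0.46. BAG3 was at 86.85 CPM in IL-15 replicate 3 (pig 13, site 12e), against 69.9 to 70.9, and JAK1 at 188 CPM in IL-15 replicate 2 (pig 14, site 12c), against 216.7 to 220.01.

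The control biopsy from pig 13 site 7b carried high S100A8, SOCS3, IL6 and CXCL8 together with low COL1A1. Against the other pig 13 control the median log2 difference was -1.50 ± 0.34 (SD over members) for hair follicle markers, 0.76 ± 0.40 for MHC class II, 0.72 ± 0.69 for monocytes and 0.62 ± 0.53 for T cells. That other control, from site 6b, had the lowest scores of all biopsies for MHC class II (-0.87), monocytes (-0.74), T cells (-0.90) and the inflammatory list (-1.27). The differences of these lists can therefore not be ascribed to site 7b alone. A swap with an injected library was argued against by HOXA9, HOXA10 and HOXC10, none of which exceeded 0.1968 of the lowest injected biopsy there. An unrecorded injection or local inflammation at that site was not tested. More epidermis and less dermis may account for its keratin and collagen levels, and the inflammatory list lay 1.0935 ± 1.41 above the other pig 13 control in its median, against 0.58 ± 0.56 (SD over members) for differentiated keratinocyte markers, a gap too small to decide. No biological explanation was tested, since the design gives none for a single uninjected site.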

How the results depend on the processing

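The covariate settings were chosen only after the results were seen, as were the values of single lists given here. HOXA10, HOXA9 and HOXC10 stayed called in all 18 settings planned for single genes, with the highest adjusted p at 0.0425, 0.0114 and 0.025. PTX3, RGS16, SPSB1 and CHAC1 kept their direction and were called in 11, 12, 12 and 10 of them. Against 7 genes higher and 0 lower in the main test, the DESeq2 test called 48 higher and 10 lower, sums per pig and treatment (1 residual degree of freedom) 4 and 1, pig 13 alone 34 and 4, pig 14 alone 16 and 1, and a test against a 1.5-fold change 3 and 0. With no replicate block for the pig the fit called 6 higher, 0 lower and 9 lists, losing CHAC1 alone. Leaving out 1 biopsy in turn gave 3 to 19 higher, 0 to 1 lower, 0 to 318 interaction genes and 9 to 15 lists, where the biopsy left alone in its pig and group was assumed to vary like the others. Interaction genes rose from 0 to 8 without a count filter and to 86 with DESeq2. List calls fell from 9 to 0 with an estimated correlation and with fry. Scaling by DESeq2 size factors or library size, the stricter filter and removal of mitochondrial and rRNA genes each left the same 7 genes called. With a keratinocyte or adipocyte score as covariate 5 or 10 genes were called higher and 9 lists either way, but not the same ones. With the keratinocyte score PTX3, RGS16 and the neutrophil (adjusted p = 0.132) and adipocyte (0.454) lists were lost, and basal keratinocytes (0.00015) and red blood cells (0.004) gained. With the adipocyte score the adipocyte list was lost (0.76) and basal keratinocytes gained (0.00026). Some genes near 0 turned sign without being called. With quality weights IL2RG had 0.025, IL2RB 0.026, SOCS1 0.013 and JAK3 0.013, with the pig as a random effect JAK3 had 0.041, and without the pig block IL15 had -0.025. With 1 biopsy left out IL15 ranged from -0.13 to 0.33, JAK1 from -0.026 to 0.13, IL2RB from -0.18 to 0.061, SOCS1 from -0.092 to 0.049 and JAK3 from -0.27 to 0.14. Of the 18 lists not called, 12 turned direction when some single biopsy was left out, and gland and monocyte markers then passed without control replicate 2. Their camera adjusted p over the biopsies left out ran from 0.015 to 0.965 for glands, 0.0225 to 0.695 for monocytes, 0.0687 to 0.759 for T cells, 0.0044 to 0.923 for MHC class II, 1.1e-05 to 0.896 for basal keratinocytes and 0.0015 to 0.544 for cell cycle. They ran from 0.0013 to 0.893 for cytotoxic effectors, 0.0083 to 0.943 for fibroblast matrix, 0.00299 to 0.83 for interferon gamma response, 0.243 to 0.972 for mast cells, 0.0319 to 0.931 for receptor components and 0.053 to 0.893 for red blood cells. With direction turned and no call, monocytes had an adjusted p of 0.955 without the pig block and 0.622 with the keratinocyte score, cell cycle 0.622 with that score and receptor components 0.795 with the adipocyte score. Without direction turned, lists of type 2 and atopic dermatitis genes, smooth muscle, skeletal muscle and B cells also passed without some single biopsy, with the lowest adjusted p at 0.0064, 0.015, 0.0185 and 0.0453. The cause was not tested for any of these changes. At this depth HOXA10 rests on 1 to 4 counts per control biopsy, which limits its fold change.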

Other observations

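The comparison of the pigs, the splits and the tests of explanations in this part were chosen only after the results were seen. The 2 pigs differed far more than the treatments. With treatment in the model, edgeR called 1270 genes higher in pig 14 and 863 higher in pig 13, a comparison of 2 animals only. Interferon-induced genes stood out in pig 14, where CXCL9, a chemokine induced by interferon gamma, was at 40.9 ± 11.7 CPM against 1.36 ± 0.44 CPM in pig 13 (SD, n = 4 biopsies), GBP1 at 131 ± 31.6 against 26.0 ± 6.07 and the tryptophan-degrading enzyme IDO1 at 5.66 ± 1.69 against 0.27 ± 0.14. Of 28 tested interferon gamma response genes 23 were called higher in pig 14 and none lower (adjusted p = 2.4e-36 by camera, and adjusted p = 0.186 with an estimated correlation). Of 10 MHC class II genes 9 were called higher there and of 20 T cell markers 11, such as CD3E at 5.61 ± 1.64 against 1.52 ± 0.38 CPM (both lists adjusted p = 0.186 with an estimated correlation). Fry's directional test passed the interferon gamma response list (adjusted p = 0.0054) and the MHC class II and T cell lists (adjusted p = 0.0132 for both). It too compares 2 animals only.

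Beta globin, HBB, was at 364 ± 132 CPM in pig 14 and 12.0 ± 6.57 CPM in pig 13, and ALAS2, an enzyme of heme synthesis in red cells, at 16.6 ± 6.03 and 1.15 ± 0.52 CPM. COL6A5, a collagen VI chain, was at 67.8 ± 13.1 against 6.65 ± 0.47 CPM. The Y-linked genes KDM5D and ZFY were at 23.0 ± 2.56 and 27.7 ± 1.70 CPM in pig 13 and at 0.019 ± 0.038 and 0.58 ± 0.12 CPM in pig 14. These are the levels of a male pig 13 and a female pig 14. The comparison of the pigs and the interaction of pig and treatment can therefore not be separated from sex. The split by pig called 2325 genes with no other term in the model, and none of the 34 other splits of the 8 biopsies into 4 and 4 called more than 6, so 1 of 35 splits gave as many. In the same fit the pig split called 15 lists, and 13 of the 35 splits gave at least 15, up to 17.

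HOXA10, HOXA9 and HOXC10 were higher at injected sites. Scaling was argued against as their source, since a factor per library shifts all genes alike, while the lowest of their log2 fold changes lay 2.862 above the median of all genes (SD over all genes 0.30). Different positions of the sites on the body may account for them, and so may a response to IL-15 or to the injection. These cannot be told apart, since 0 of the 8 biopsies broke the link between site number and treatment. Splits that keep 2 biopsies of each pig on both sides number 18, too few for a share under 0.05. The real one called 7 genes against at most 64 in another, which exchanged 1 injected and 1 control biopsy of pig 14. In that other split the adipocyte score, picked after its values were seen, was 0.32 to 0.85 on 1 side and -0.85 to 0.13 on the other. The cause of its 64 calls was not tested.

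The cytokine and NF-kB list had a median log2 fold change of 0.69 and was called by camera, but not with an estimated correlation (adjusted p = 0.324) or with fry (adjusted p = 0.229). The lists of neutrophils, monocytes and T cells showed no rise in the injected biopsies, with a highest median of -0.0199 ± 0.18 (SD over members). They cannot exclude more leukocytes there, since the monocyte score ran from -0.74 to 0.67 among the controls alone. The monocyte and T cell lists each turned direction in 3 of the fits with 1 biopsy left out. With the keratinocyte score as a covariate the median was 0.70, which does not decide on a different share of epidermis. That score averaged basal and differentiated keratinocyte markers, whose medians went in opposite directions (0.097 and -0.42), so it could hide such a difference. Injection itself in place of IL-15 remains open, since the series holds 0 vehicle-injected biopsies, and the 2 cannot be told apart. Chance was not excluded for the number of list calls, with at least 9 in 27 of the 35 splits without the pig in the model and up to 17 in another, and 18 pig-balanced splits are too few for a share under 0.05, where 11 gave at least 9 and the highest other gave 14.

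Without the pig in the model the real split called 6 genes, and 2 of the 35 splits gave as many, so chance was not excluded by that count. The other one was the split by pig, with 2325 genes, which follows the difference between the animals, and the remaining splits called at most 1. With the pig in the model the real split called 7 and the highest other 64.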
